A study of Oryza sativa with 36 samples.

How the data were processed

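RNA was measured in rice (Oryza sativa) tissue that the labels describe as axillary meristems, from 2 cultivars, Takanari and NIL-MP3. Each library carries a tissue label, AM1, AM2, AM3, AM4, AM5 or SAM, which the labels do not spell out, and a library number from 1 to 18 within its cultivar. Plants grew in chambers in a cycle of 14 h dark (25 °C) and 10 h light (27 °C), per the labels' protocols. Libraries followed CEL-Seq2, which tags each transcript near its 3' end with a molecular identifier (UMI) and amplifies by in vitro transcription. They started from 100 pg of RNA and took 11 to 15 cycles of PCR, per the labels' protocols.

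The deposited values were counts of molecules per locus, 55801 loci by 35 libraries, whole numbers that were not normalized. Bowtie2 and Subread 2.1 are named, per the submitters' processing notes, with no role or order. The genome build, the gene annotation and the handling of reads shared by near-identical or overlapping loci are not given in the sources used here. The labels list 36 libraries. Takanari SAM library 18 was left out of the counts by the submitters because its reads did not align, per the labels, so that group had 2 libraries and each of the other 11 groups had 3.

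Loci were identified by their identifiers as the file gives them. None of the 55801 identifiers had a match in the gene table used here (0 matched), so no gene name, function or gene list could be assigned, and gene list tests planned before the data were examined were not run. The chromosome of a locus was read from its identifier. The rule fixed before the data were examined took the loci with the lowest p-value in each direction of a main comparison. Because the files do not pair identifiers with names, the text prints the first 2 in each direction for 3 main comparisons, 12 loci in all, and the genes that the rule listed by symbol are not reported.

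The total count per library ranged from 77362 to 224706, with a median of 143050. Of the 24225 loci with any count, 6943 passed edgeR's filterByExpr over the 12 groups of cultivar and tissue, with its minimum count of 10. These loci held 84.5% to 87% of each library's counts. TMM factors lay between 0.89 and 1.04. CPM, counts scaled by library size, were computed from the deposited counts with library sizes summed over the tested loci and TMM factors. Molecules of a UMI library are counted once, so PCR copies do not add to them, and a count of 0 allows up to 3 counts.

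The main test was edgeR's quasi-likelihood F test (edgeR 4.0.16 in R 4.3.3) with robust dispersion, 1 mean per group and no covariate, and Benjamini-Hochberg adjustment at 0.05. The common biological coefficient of variation was 0.248. Contrasts were the mean difference NIL-MP3 minus Takanari over 6 tissues and in each tissue, the mean of the AM groups minus the mean of the SAM groups, the slope over AM1 to AM5 per label number, and 3 interactions of cultivar with tissue. The standard error of a log2 change was its size divided by the square root of F. The slopes within each cultivar, the contrasts of AM1 and AM5 with SAM, the position score and the analyses by set of library numbers were added after the data were examined. All adjusted p-values of single loci below are from this test, unless another tool is named.

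The position score of a library placed it along the slope. Its weights were the slopes of the loci called in the other cultivar. The score was the weighted sum of the library's log2(CPM) deviations (prior count 2) from the mean of the AM groups of its own cultivar, divided by the sum of squared slopes. Its unit would be 1 label number if both cultivars had equal fitted slopes at these loci and the prior count shrank no value. The score rose by less, a mean of 0.487 per label number in NIL-MP3 and 0.733 in Takanari. This does not show that the cultivars differ in slope, because the weights came from loci chosen for their slopes. A second score, used as a covariate and for slopes per set, took 1300 loci with a pooled slope past the threshold that were not called between the cultivars. It was centred on the mean of all 35 libraries, so a shift between the cultivars stayed in it. Differences between tissues in the position score, and not in the second score, were tested by exact two-sided permutation within cultivars. Libraries were shuffled without regard to their library numbers. Placement on chromosomes was tested with Fisher's exact test, two-sided.

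The labels do not say whether libraries came from separate plants, so p-values measure the spread between these samples, which may be technical. Library numbers run in sets of 6 (1 to 6, 7 to 12, 13 to 18), each with 1 library of every tissue, and no set spans both cultivars by label. Libraries of a set deviated together from their group means, so the set was also fitted as a random effect in limma 3.58.1 and counts were also summed per set. The cultivar of each set was tested in the AM libraries at 50 loci chosen from the 2 other sets of its cultivar against 1 set of the other, by the share of that difference found between the set and the 2 sets not used. No pair of libraries held identical counts, and the lowest chi-square per degree of freedom between replicates was 1.65.

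The fits were tested on simulated counts drawn with the real mean of each locus over all libraries, and the real library sizes and dispersions. Libraries were drawn independently, without the spread that real libraries of a set share. Recovery of the cultivar difference over all tissues may therefore be lower in the real data. For the cultivar difference over all tissues, 82% of loci with a simulated log2 change of 1 were recovered. For the cultivar difference in AM3 alone, recovery was 63% at a log2 change of 2 and 89% at 3. For AM against SAM it was 51% at 1 and 85% at 2, and for the slope 53% at 0.25 and 100% at 0.5 per label number. For the interaction of cultivar with AM or SAM, 51% of loci with a log2 change of 2 and 86% with 3 were recovered.

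Alternatives fixed before the data were examined were RLE and upper quartile scaling, no filter, a stricter filter (10 counts in 50% of the libraries), DESeq2 1.42.0, limma voom with quality weights, a replicate block of 3 or 6 levels, single tissues fitted alone, and each library left out in turn. A rule against libraries under 20% of the median total removed 0 libraries.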

Results

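Expression was measured in 35 CEL-Seq2 libraries of rice meristem tissue, 18 from NIL-MP3 and 17 from Takanari. Takanari is a high-yielding indica rice, and the name NIL-MP3 marks a near-isogenic line. From general knowledge of the line, which the labels do not give, MP3 is a locus on chromosome 3 that affects the number of panicles. Each cultivar was sampled as AM1 to AM5 and SAM, with 3 libraries per group and 2 for Takanari SAM. Total counts ran from 77362 in Takanari AM5 replicate 1 to 224706 in NIL-MP3 SAM replicate 18, and 12324 to 15662 loci had a count. The AM5 libraries had the lowest mean total of the 6 tissues, 110700 ± 29300 (SD, n = 6), and the SAM libraries the highest, 163500 ± 42360 (SD, n = 5).

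The AM number was the main axis of variation. The first principal component of the 1000 most variable loci held 28.7% of the variance, and the next components held 7.94% and 6.04%. On the first component the AM5 libraries lay between -29.1 and -11.6. The AM1 libraries lay between 12.1 and 18.8, except NIL-MP3 AM1 replicate 17 at -4.22. The SAM libraries lay between 0.4 and 14.9, on the AM1 side. On the second component both AM5 libraries numbered 1, which had the lowest totals, lay at 18.4 and 19.6, apart from the other AM5 libraries at -6.93 to 7.29.

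The first comparison asked which loci changed with the AM number. LOC_Os03g06240, on chromosome 3, rose from a mean of 460 CPM in AM1 (range 362 to 641, n = 6) to 1650 ± 319 CPM in AM5 (SD, n = 6), a fitted 3.74-fold increase over 4 steps. LOC_Os03g44620, also on chromosome 3, rose 2.6-fold, from 677 ± 77.7 to 1680 ± 290 CPM (SD). In the opposite direction, LOC_Os01g06010 on chromosome 1 went from 1080 ± 213 CPM in AM1 to 365 ± 88.6 CPM in AM5, a 3.07-fold decrease. LOC_Os08g40170 on chromosome 8 went from 370 ± 91.5 to 68.8 ± 36.5 CPM, a 5.47-fold decrease. In SAM these 4 loci had 518 ± 112, 819 ± 102, 955 ± 143 and 345 ± 36.1 CPM (SD, n = 5).

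In edgeR's quasi-likelihood test the slopes per label number were 0.48 ± 0.040 (SE, adjusted p = 3.18e-14) for LOC_Os03g06240 and 0.34 ± 0.035 (adjusted p = 4.97e-11) for LOC_Os03g44620. They were -0.40 ± 0.039 (adjusted p = 4.32e-12) for LOC_Os01g06010 and -0.61 ± 0.064 (adjusted p = 1.04e-10) for LOC_Os08g40170. Across all tested loci, 1331 of 6943 had a slope past the threshold, 650 rising and 681 falling, with a median size of 0.281 on the log2 scale per label number. At an unadjusted p under 0.05 there were 2126 loci, against 347 expected by chance. The count of called loci was 819 without the AM5 libraries and 785 after every library was thinned to the lowest total. All 4 named slopes stayed past the threshold in both, but that of LOC_Os08g40170 was -0.3816 without the AM5 libraries.

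**Figure D1:**
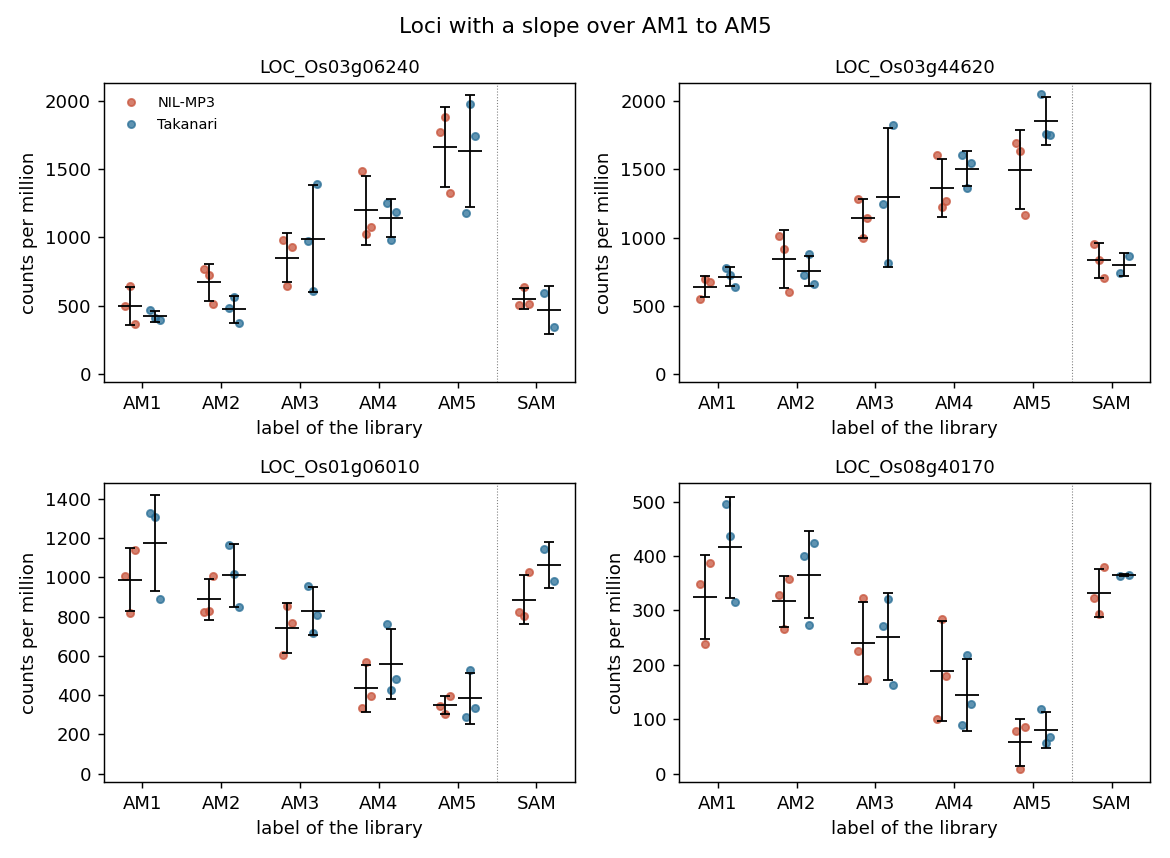
CPM of the 2 rising (upper panels) and 2 falling (lower panels) loci in each library, by tissue label, with NIL-MP3 in red and Takanari in blue; bars are the group mean ± SD. The SAM values of all 4 loci lie near those of AM1 and AM2 and not near those of AM5.

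The direction of the slopes was shared by the cultivars. LOC_Os03g06240 rose by 0.43 ± 0.056 per label number in NIL-MP3 and by 0.52 ± 0.057 in Takanari (SE), and LOC_Os01g06010 had slopes of -0.40 ± 0.055 and -0.40 ± 0.054. For LOC_Os03g44620 the slopes were 0.32 ± 0.050 and 0.37 ± 0.050, and for LOC_Os08g40170 they were -0.60 ± 0.093 and -0.62 ± 0.088. Fitted within cultivars, 352 loci had a slope in NIL-MP3 (167 rising, 185 falling) and 792 in Takanari (383 rising, 409 falling). Of the rising loci 120 were called in both, against 9.21 expected of independent lists (Fisher's exact test, p = 3.07e-119), and of the falling loci 144 against 10.9 (p = 4.98e-149). None was called in opposite directions (0 loci), and across the 6943 loci, which are not independent replicates, the 2 sets of slopes had r = 0.648. The count in NIL-MP3 was 180 without NIL-MP3 AM1 replicate 5, 219 without NIL-MP3 AM5 replicate 13 and 112 without AM5. With a replicate block of 6 levels it was 575, and 402 loci were shared. The count in Takanari was 513 without Takanari AM1 replicate 17 and 361 without AM5, and the 264 shared loci became 142, 158 and 69 without NIL-MP3 AM1 replicate 5, NIL-MP3 AM5 replicate 13 and the AM5 libraries.

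A position score summarised the falling and rising loci in each library, with weights from the other cultivar. In Takanari it went from -1.21 ± 0.0843 in AM1 and -1.06 ± 0.158 in AM2 to -0.0623 ± 0.531 in AM3, 0.822 ± 0.118 in AM4 and 1.51 ± 0.146 in AM5 (SD, n = 3). In NIL-MP3 the scores were -0.847 ± 0.591, -0.586 ± 0.528, -0.0722 ± 0.431, 0.416 ± 0.556 and 1.09 ± 0.368 in the same order. The SAM libraries scored -1.03 ± 0.075 in Takanari (n = 2) and -0.667 ± 0.35 in NIL-MP3 (n = 3). The SAM mean lay between those of AM1 and AM2 in NIL-MP3 and next to that of AM2 in Takanari. AM1 to AM5 were strictly ordered in 5 of 6 sets of library numbers, and in Takanari numbers 7 to 12 AM2 lay below AM1.

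The score of AM5 lay above that of SAM by 1.76 units in NIL-MP3 and 2.55 units in Takanari, on different loci. The average over the cultivars was 2.15 (exact permutation test within cultivars, two-sided, p = 0.005, the smallest that the 200 splits allow, adjusted p = 0.0125 over 5 comparisons). The differences below are such averages too. AM4 lay above SAM by 1.47 (exact p = 0.005, adjusted p = 0.0125) and AM3 by 0.783 (exact p = 0.02, adjusted p = 0.0333). The differences of AM1 and AM2 from SAM were -0.179 (exact p = 0.375, adjusted p = 0.469) and 0.0292 (exact p = 0.885, adjusted p = 0.885). Neither passed the threshold, which does not show that these tissues were alike. The permutations did not pair libraries by their set of library numbers, so the p-values take in the spread between sets.

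**Figure D2:**
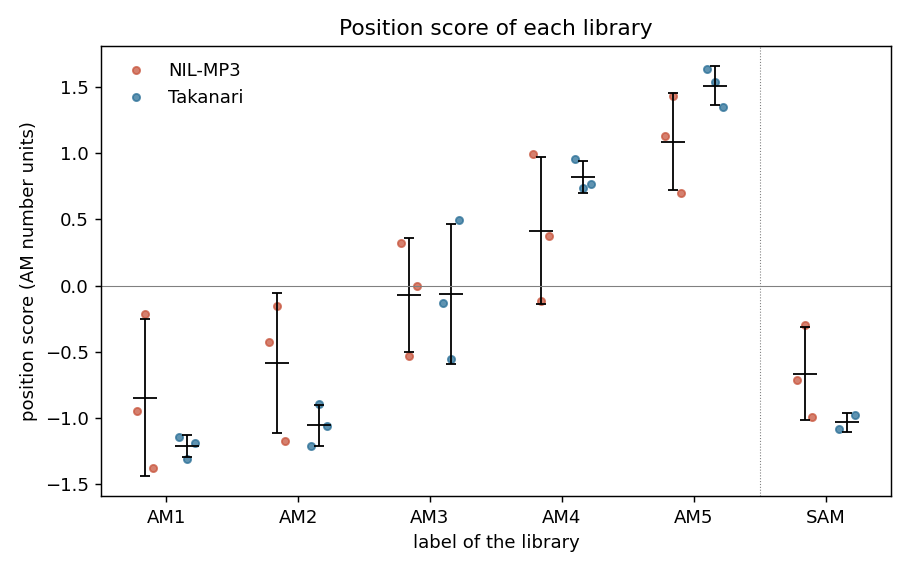
Position score of each library by tissue label and cultivar (NIL-MP3 red, Takanari blue). Bars are the group mean ± SD. The score rose by less than 1 unit per label number, which does not show that the slopes of the cultivars differ. Group means run from -1.21 (AM1) to 1.51 (AM5) in Takanari and from -0.847 to 1.09 in NIL-MP3, and the SAM means are -1.03 and -0.667.

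The second comparison asked which loci set the libraries labelled AM1 to AM5 apart from SAM. LOC_Os06g11840, on chromosome 6, had 137 ± 84.1 CPM in the AM libraries (SD, n = 30) and 41.1 ± 19.2 CPM in SAM (n = 5). LOC_Os06g46890, on the same chromosome, had 61.5 ± 21.8 CPM in AM and 17.6 ± 15.1 CPM in SAM, from 14 counts in all SAM libraries. LOC_Os07g37400 and LOC_Os01g04330 were higher in SAM, at 180 ± 36.3 and 314 ± 83.5 CPM, than over the AM libraries, at 78.1 ± 97.2 and 96.4 ± 89.1 CPM. Both also went down along the AM series, LOC_Os07g37400 from 217 ± 139 CPM in AM1 to 16.6 ± 23.5 CPM in AM5 (SD, n = 6) and LOC_Os01g04330 from 193 ± 129 to 31.2 ± 34.1 CPM.

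In edgeR's quasi-likelihood test the log2 difference AM minus SAM was 1.5 ± 0.31 (SE, adjusted p = 0.00452) for LOC_Os06g11840 and 2.33 ± 0.50 (adjusted p = 0.00603) for LOC_Os06g46890. It was -1.89 ± 0.29 for LOC_Os07g37400 and -1.96 ± 0.28 for LOC_Os01g04330 (adjusted p = 7.42e-05 for both). With a replicate block of 6 levels, which fits the sets within each cultivar, 282 loci passed. In the main test, without a block, 94 loci passed, 27 higher and 67 lower in AM, and 857 had an unadjusted p under 0.05. The count fell to 9 without Takanari SAM replicate 12, 29 without Takanari SAM replicate 6, 33 and 59 without NIL-MP3 SAM replicates 12 and 6, 27 without the AM5 libraries and 37 in thinned counts, and was 155 with no filter, 150 with limma voom with quality weights and 214 with the set of library numbers as a random effect. Without Takanari SAM replicate 12, LOC_Os06g11840 (adjusted p = 0.0609), LOC_Os06g46890 (0.294) and LOC_Os01g04330 (0.0609) did not pass. The log2 difference of LOC_Os06g46890 was 1.737 without that library and 3.503 without Takanari SAM replicate 6. LOC_Os06g11840 also did not pass without Takanari SAM replicate 6 (0.0873) or the AM5 libraries (0.0539).

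Far more loci passed the threshold against SAM in AM5 than in AM1. AM5 against SAM gave 709 loci, 384 higher and 325 lower in AM5, and AM1 against SAM gave 10, of which 8 were higher in AM1. The share higher in AM5, 54.2%, was not stable: it was 43.2% with no filter and 50% without the 2 libraries of lowest total. The called loci differed by a median of 2.7-fold between AM5 and SAM. AM5 was not contrasted with AM1 directly, and no test compared the counts of loci. The slopes above tested a linear change over AM1 to AM5. Without Takanari SAM replicate 12 the counts were 382 and 1. The AM1 count was also 3 to 6 without NIL-MP3 SAM replicate 12 (3), NIL-MP3 SAM replicate 6 (4), Takanari SAM replicate 6 (6), Takanari AM1 replicate 5 (3) and Takanari AM1 replicate 17 (3). With upper quartile scaling 6 loci differed between AM1 and SAM, 66.7% of them higher in AM1, against 80% with TMM. The AM1 count was larger with no filter (16) and with a replicate block of 3 (18) or 6 levels (27).

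**Figure D3:**
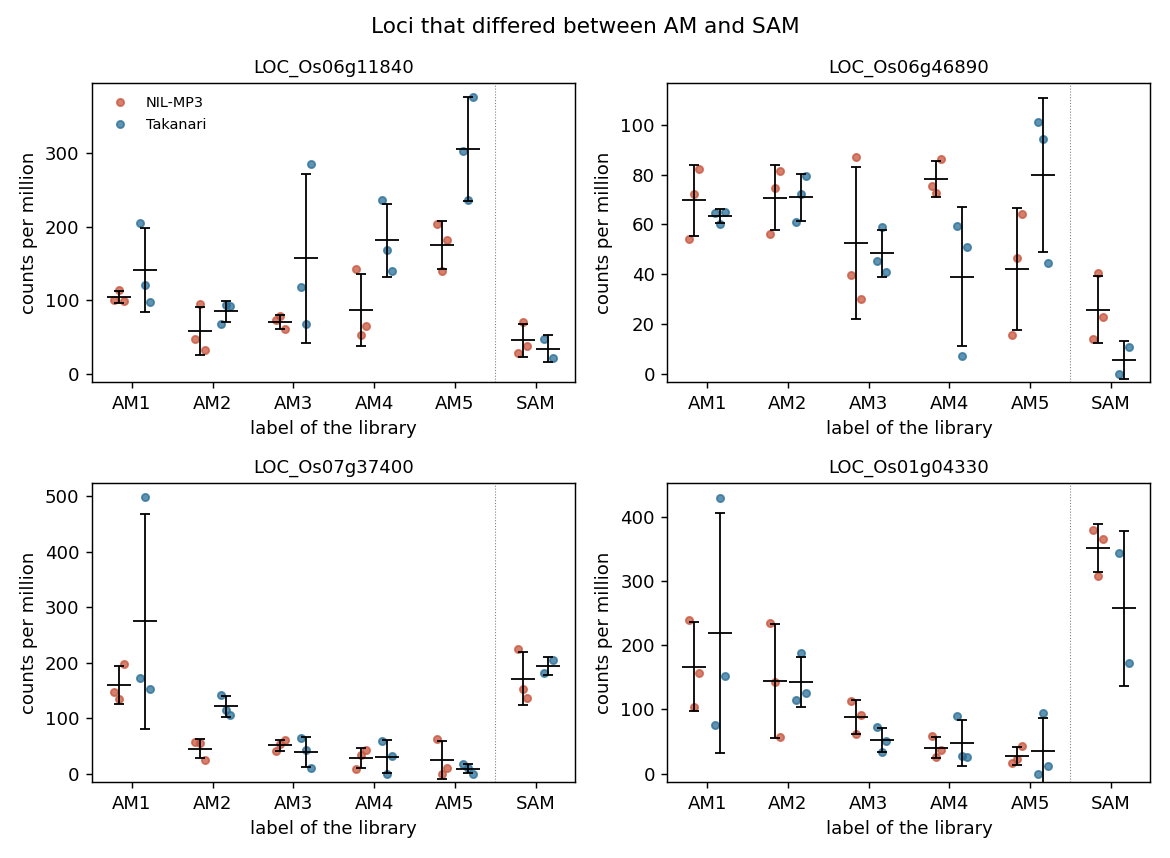
CPM of the 2 loci higher in AM (upper panels) and 2 lower in AM (lower panels) in each library, by tissue label, with NIL-MP3 in red and Takanari in blue; bars are the group mean ± SD. The lower panels show LOC_Os07g37400 and LOC_Os01g04330 falling from AM1 to AM5, with SAM at 180 and 314 CPM.

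The last of the 3 main comparisons set NIL-MP3 against Takanari over all 6 tissues. LOC_Os01g57968, on chromosome 1, was lower in NIL-MP3, at 1270 ± 386 CPM (SD, n = 18) against 2270 ± 754 CPM in Takanari (n = 17). LOC_Os05g22840, on chromosome 5, was also lower, at 453 ± 185 against 1100 ± 379 CPM. LOC_Os02g57250 on chromosome 2 was higher in NIL-MP3, at 225 ± 57.7 against 130 ± 29.5 CPM. LOC_Os03g18870 on chromosome 3 had 46.4 ± 29.1 CPM in NIL-MP3 and 8.1 ± 9.16 CPM in Takanari, from 109 and 19 counts. Each of these 4 loci, chosen for the mean difference over these tissues, had the same sign in 6 of 6 tissues.

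In edgeR's quasi-likelihood test the log2 difference was -0.83 ± 0.090 (SE, adjusted p = 9.63e-10) for LOC_Os01g57968 and -1.26 ± 0.15 (adjusted p = 4.76e-06) for LOC_Os05g22840. It was 0.75 ± 0.14 (adjusted p = 0.0011) for LOC_Os02g57250 and 2.80 ± 0.50 (adjusted p = 4.79e-04) for LOC_Os03g18870. In total 90 loci passed, 61 higher and 29 lower in NIL-MP3, and 957 had an unadjusted p under 0.05. The share higher in NIL-MP3, 67.8%, was not stable: it was 36.4% with the set as a random effect, 47.8% and 51.1% without NIL-MP3 library numbers 13 to 18 and 7 to 12, and 55.6% with the stricter filter.

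Sets of library numbers lay within cultivars, and most of this count was lost when they were taken into account. With the set as a random effect in limma, 11 of the 81 loci called by limma without it stayed called (consensus correlation 0.127), among them LOC_Os01g57968 (adjusted p = 1.16e-05) and LOC_Os05g22840 (4.17e-05) and not LOC_Os02g57250 (0.0741) or LOC_Os03g18870 (0.0794). The log2 differences hardly moved, from 0.711 ± 0.139 to 0.698 ± 0.177 for LOC_Os02g57250 and from 1.98 ± 0.421 to 1.97 ± 0.507 for LOC_Os03g18870 (SE), and these calls ended because the standard errors widened. With the AM counts summed per set, 3 sums against 3, edgeR called 2 loci, both lower in NIL-MP3, among them LOC_Os05g22840 (adjusted p = 0.00846), and LOC_Os01g57968 did not pass (-0.789 ± 0.151, SE, adjusted p = 0.0618). Of the 9 other assignments of these sums, 2 also called 2 loci. When whole sets were reassigned, 3 of the 9 other assignments of the 6 sets to 2 arms of 3 called 160 to 245 loci, more than the 90 of the cultivars. The count was 422, 45 and 23 without NIL-MP3 library numbers 1 to 6, 7 to 12 and 13 to 18, and 70, 44 and 44 without those of Takanari. It was 29 in thinned counts, 50 without the AM5 libraries and 143 with no filter. It was 53 and 58 without Takanari SAM replicates 12 and 6, 58 without NIL-MP3 SAM replicate 18 and 145 without NIL-MP3 AM1 replicate 5.

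**Figure D4:**
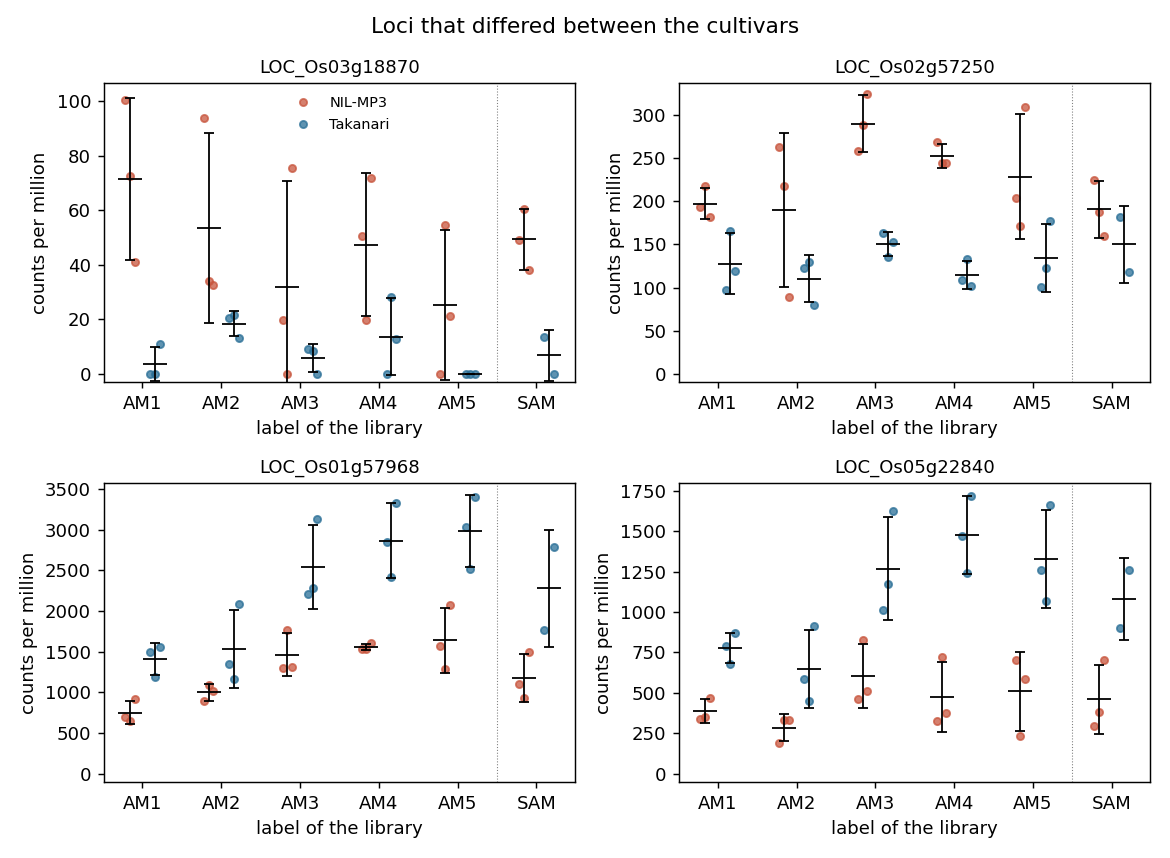
CPM of the 2 loci higher (upper panels) and 2 lower (lower panels) in NIL-MP3 in each library, by tissue label, with NIL-MP3 in red and Takanari in blue; bars are the group mean ± SD. LOC_Os01g57968 and LOC_Os05g22840 have a lower mean in NIL-MP3 in each of the 6 tissues.

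Within single tissues no locus passed the threshold between the cultivars (0 in each of the 6 tissues with edgeR, and 0 with DESeq2 and limma voom). The unadjusted p was under 0.05 at 404 loci in AM1, 301 in AM2, 250 in AM3, 289 in AM4, 363 in AM5 and 284 in SAM, where 347 are expected by chance. The smallest adjusted p was 0.103, in AM5. With 3 libraries a group, 63% of loci with a simulated log2 difference of 2 were recovered in AM3. Other settings called 1 to 5 loci in AM4, 1 to 3 in AM5, 1 to 2 in SAM and 1 in AM2.

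Whether the cultivar difference itself varied between tissues was tested with 3 interactions, and none called a locus (0 each with edgeR, DESeq2 and limma voom). The unadjusted p was under 0.05 at 125 loci in the joint test over tissues, 197 for AM against SAM and 296 for the slope over AM1 to AM5, where 347 are expected by chance. Among the 12 named loci the smallest interaction p over tissues was 0.0959, for LOC_Os06g46890 (adjusted p = 0.948 over the 12 loci). The mean slope per set of a score from 1300 loci with a slope in these same libraries, pooled over the cultivars, was 0.68 ± 0.114 in NIL-MP3 and 0.844 ± 0.0566 in Takanari (SD, n = 3 sets each; exact permutation test, two-sided, p = 0.2, with 0.1 the smallest possible). With the position score above it was 0.487 ± 0.106 and 0.733 ± 0.0306 (SD, n = 3 sets each; exact permutation test, two-sided, p = 0.1), on different loci in the 2 cultivars and so not on 1 scale.

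Chromosome 3 was examined because the MP3 locus lies there. Of 1045 tested loci on chromosome 3, 17 differed between the cultivars (1.63%), 13 of them higher in NIL-MP3, against 1.24% on the other chromosomes. The odds ratio was 1.32 (95% interval 0.726 to 2.27; Fisher's exact test, two-sided, p = 0.299). No window of 100 neighbouring tested loci passed the threshold, and the lowest adjusted p was 0.135, on chromosome 12.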

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

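Thinned counts, limma voom without weights, the set as a random effect, sums per set, the position score as a covariate, and the settings without AM5, without the 2 libraries of lowest total or without a set of library numbers were chosen after seeing the data, as were the results within cultivars, those of AM1 and AM5 against SAM and the shared loci. The 12 named loci kept their direction in each of their 583 values under other settings, and 573 of these stayed past the threshold, 10 did not and 0 reversed. Most of these values came from leaving out 1 library of the same data. A setting in which a locus was filtered out or had no adjusted p is not counted. LOC_Os03g18870 had 50 values against 55 for LOC_Os01g57968, and LOC_Os06g46890 had 46 against 49 for LOC_Os01g04330. The odds ratio of chromosome 3 was 1.41 at a threshold of 0.01 and 1.51 with DESeq2 calls, and no position score crossed the threshold with a prior count of 0.5 or 5 or in thinned counts. A wrong cultivar on a set was tried in 6 ways, at 2 named loci chosen with the set included, on scores from 50 loci and from all loci called without the set, at the 3 loci of lowest p without the set, against sets unused in choosing 50 loci, and by set means at 2 named loci. The test with unused sets was fixed before its values were seen, except that it was read as undecided after 0 of 6 sets passed it. The bound for chromosome 3 was changed from an upper end under 3 to one under 1 after the interval was seen.

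Counts of called loci that moved by over 1.5 times were as follows. With no filter, 143 loci differed between cultivars over all tissues (90 in the main test), 1 in AM2, 4 in AM4, 3 in AM5 and 2 in SAM, 155 differed between AM and SAM (94) and 16 between AM1 and SAM (10). AM1 against SAM gave 6 with upper quartile scaling, 4 with the stricter filter, 6 and 2 with limma voom with and without quality weights, and 2 in thinned counts. Limma with quality weights called 150 for AM against SAM. With the set as a random effect, limma called 11 between cultivars, 1 in AM4 and 214 for AM against SAM. Fitted alone, AM4 gave 5 and SAM 1 between cultivars. Thinned counts gave 29 between cultivars, 37 for AM against SAM, 785 for the slope (1331) and 456 for AM5 against SAM (709), with fewer molecules by construction. Without AM5 the counts were 50 between cultivars, 27 for AM against SAM, 819 for the slope, 112 in NIL-MP3 (352), 361 in Takanari (792) and 69 shared (264). Between cultivars, 422, 45 and 23 differed without NIL-MP3 library numbers 1 to 6, 7 to 12 and 13 to 18, and 44 without Takanari library numbers 7 to 12 and 44 without 13 to 18, and sums per set gave 2. With the position score as a covariate the count was 91, of which 72 were among the 90. Except for thinning and left-out libraries, the cause was not tested.

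Leaving out 1 library at a time gave 53 to 145 loci between cultivars over all tissues, 0 to 1 in AM4 and in AM5, 9 to 110 for AM against SAM, 1080 to 1457 for the slope, 180 to 456 in NIL-MP3, 513 to 831 in Takanari, 142 to 308 shared, 1 to 15 for AM1 against SAM and 382 to 749 for AM5 against SAM. Where 1 Takanari SAM library remained, it was assumed to vary like the other groups.

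The same library number in both cultivars did not pair libraries: the 17 pairs had a median correlation of deviations of 0.00153 and 2 were over 0.1. Within a cultivar the libraries of a set had a median of 0.144, with 57 of 85 pairs over 0.1 and a lowest of 0.0358, and 35 of 35 libraries deviated most like their own set, a hint from the data and not from the design. A replicate block of 3 levels gave 2 loci between cultivars in AM4, 3 in AM5 and 18 for AM1 against SAM, and a replicate block of 6 levels gave 282 for AM against SAM, 27 for AM1 against SAM, 575 for the slope in NIL-MP3 and 402 shared loci. No other count moved by over 1.5 times under the block. Gene list tests were not run because no identifier was matched to a gene, and the alternative without libraries of low total removed no library.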

Other observations

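The overlaps, neighbour counts and chromosome counts in the next paragraphs, the test of chromosome 3 as a segment, the shift of the pooled score, the tests of the cultivar of a set and the reassignment of whole sets were chosen after the results were seen. The thinned counts and the analyses by set were added after the counts had been examined.

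The loci that set AM apart from SAM were mostly loci that also changed along AM1 to AM5. Of the 94 loci, 66 had a slope past the threshold, against 18 expected of independent lists (Fisher's exact test, p = 2.87e-27), and in 65 the difference from SAM and the slope had the same sign. LOC_Os07g37400 and LOC_Os01g04330 were among them, with adjusted slope p-values of 1.08e-08 and 6.99e-06, and LOC_Os06g46890 was not (0.635). Of the 90 loci that differed between cultivars, 31 had a slope (34.4%, against 19% of the other loci; Fisher's exact test, p = 0.000613), and in 11 of these the signs were opposite. Both Fisher tests take loci as independent, and the lists compared came from the same libraries. The 90 calls also left out the sets of library numbers, so an excess of slopes among cultivar differences is not established. LOC_Os01g57968, lower in NIL-MP3, rose along AM1 to AM5 in both cultivars, by 0.289 ± 0.050 per label number in NIL-MP3 and 0.307 ± 0.0485 in Takanari (SE).

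Loci next to each other among those tested changed together along the AM series more often than by chance. There were 177 neighbouring pairs called in the same direction, against a mean of 127 and a highest of 168 in 10000 shuffles of the loci (permutation p = 1e-04, the smallest the shuffles can give). The handling of reads shared by near-identical neighbours is not given in the sources used here. The same count was 1 pair for the cultivar difference (permutation p = 0.5) and 0 pairs for AM against SAM (permutation p = 1). On chromosome 12, 12 of 363 tested loci differed between cultivars, 6 in each direction (3.31%, Fisher's exact test, adjusted p = 0.0284 over the chromosomes). These are calls of the test without sets of library numbers, and the Fisher test takes them as independent. With the set as a random effect 11 of 81 limma calls stayed, so an excess on chromosome 12 is not established. Of loci with at least 20 counts in total, 2 had counts in NIL-MP3 only and 0 in Takanari only.

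The slope over AM1 to AM5 was weighed against depth and chance, since AM5 had the lowest totals. After thinning to the lowest total, the called loci kept a median of 0.982 of their slope. Random thinning leaves the expected slope of a count model unchanged, so this ratio could not have shown a role of depth. Thinning also cannot undo other traits of libraries with few molecules. Whether such traits of the AM5 libraries contributed cannot be decided from it. Only the real one (1) of 100 splits of the libraries gave as many as 1331 loci, and the highest other gave 97. The splits were likewise 1 of 100 for NIL-MP3 (352 against 13) and Takanari (792 against 246), so chance is argued against for the slopes. AM against SAM (94 against 8) and AM5 against SAM (709 against 2) also gave 1 of 100. Those splits shuffled all 6 tissue labels within a cultivar, which breaks the slope over AM1 to AM5 as well. They test for any difference between tissues and not for SAM alone, and the count for AM against SAM fell when single SAM libraries were left out. For AM1 against SAM it was also 1 of 100, but the 10 loci lay close to the 6 of the highest other split, and 1 was left without Takanari SAM replicate 12 and 2 in thinned counts. Measured expression changed with AM number in both cultivars in these libraries, and the cause stays open. A change of expression within cells and a different mix of cell types in the AM samples were not told apart. The mix was not tested because no marker gene could be named.

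In splits of single libraries 1 of 100 gave as many as the 90 loci between the cultivars (highest other 24), but 4 of 10 assignments of whole sets did, the real one included, and the larger ones, with 245, 235 and 160 loci, each placed NIL-MP3 numbers 1 to 6 with 2 Takanari sets, which points to a structure of the samples that follows the sets. Spread between sets may account for many of the 90, since 13.6% of limma calls stayed with the set as a random effect, where the differences kept a median of 1 and the standard errors grew by a median of 1.24 times. The top 50 loci of some sets kept a median of 0.0339 of their difference in the sets not used to choose them (18 choices), and the median between unused sets was 0.0865. Loci so chosen shrink by the choice alone, so this does not bear on the 90. A wrong cultivar on NIL-MP3 numbers 1 to 6 was not decided. Without them 422 loci were called, and on a score from those loci 0 of the 6 libraries lay on the NIL-MP3 side of the midpoint. On it 5 of 6 lay beyond every Takanari library of their tissue, but 6 of 6 fell short of every other NIL-MP3 library. Every set left out had 5 or 6 libraries on both counts, so these 2 counts do not bear on the label. The set kept -0.06 to 0.0767 of the difference at loci chosen without it, against up to 0.141 between Takanari sets, in a test that 0 of 6 sets passed. At LOC_Os05g22840 and LOC_Os01g57968, chosen with the set included, 6 of 6 lay below every Takanari library of their tissue, which goes against a wrong label. There 6 of 6 and 3 of 6 also lay above every other NIL-MP3 library of their tissue. The set means there, -0.806 and -0.686 from Takanari, lay within the 95% prediction ranges from 3 Takanari sets (± 1.09 and ± 0.88). Both loci were also among the 3 loci of lowest p without the set. At all 3 of those loci, only 2 of 6 libraries lay past every Takanari library of their tissue. Another count at the same 3 loci had 2 of 6 short of every other NIL-MP3 library of their tissue. A common shift along the AM axis is argued against by the fit with the pooled score as covariate, where the called loci kept a median of 0.913 of their difference; the cultivars lay 0.13 units apart on that score, which times the slopes gave a median of 0.00421 of the differences. An excess on chromosome 3 was neither shown nor excluded (odds ratio 1.32, 95% interval 0.726 to 2.27), and 73 of the 90 loci lay on other chromosomes. A cultivar effect stays open, and not only for the loci named here. LOC_Os05g22840 passed in all 55 other settings, with adjusted p up to 0.00846. LOC_Os01g57968 passed in 54 of 55 and missed with edgeR on sums per set (adjusted p = 0.0618). Most of these settings left out 1 library of the data that gave the loci, and a cultivar effect is untested beyond that.

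The position scores of NIL-MP3 differed between its sets, with means of -0.512 for numbers 1 to 6, -0.168 for 7 to 12 and 0.347 for 13 to 18 (6 libraries each), and in Takanari they were -0.235, -0.137 and 0.0328, the last over 5 libraries without SAM. An effect of unequal totals on the log2(CPM) values is argued against, since thinned counts kept 0.853 of the difference between numbers 13 to 18 and 1 to 6. Thinning does not test other traits of libraries with few molecules. A swap with the other cultivar was not decided either: a score from 50 loci in the other sets placed 5 of the 6 libraries on the NIL-MP3 side, where scores from the loci called without each other set placed 0 to 5 of its libraries on their own side, and the set kept 0.00242 to 0.103 of the difference, against up to 0.144 between Takanari sets. At the 3 loci of lowest p without the set 6 of 6 libraries lay below every Takanari library of their tissue, against 2 of 6 and 5 of 6 for the other NIL-MP3 sets at their own 3 loci, while up to 4 of 5 libraries of a Takanari set left out lay past the rest of Takanari; at LOC_Os05g22840 and LOC_Os01g57968, chosen with the set included, its means lay -1.58 and -0.912 from Takanari, outside those ranges, which goes against a swap. A difference in the stage or day of collection is a candidate explanation that was not tested, because the labels give neither.

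The shares of other splits do not bear on the remaining tests. Those tests called 0 loci, and every split gives at least 0. For the 3 interactions, which called 0 loci, 100 of 100 splits gave as many, and the highest others were 2 (joint), 1 (AM against SAM) and 3 (slope). Within AM1, AM2, AM3, AM4 and AM5 the 10 splits of 6 libraries are too few for a share under 0.05. All 10 gave at least the 0 loci of the cultivars, and the highest other was 0 in AM1 to AM4 and 1 in AM5.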
